A study of Homo sapiens with 2 samples.

How the data were processed

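SNRPA1 was profiled by irCLIP in 2 biological replicates of the MDA-231-LM2 cell line with an antibody to the endogenous protein. Per the submitters' processing notes, cutadapt 1.10 and BWA 0.7 were used with genome build hg19. Control immunoprecipitates or input libraries were not analysed here. The 2 peak lists do not keep the replicates apart. The second is pooled, per its file name, while the first names no sample, so which reads it was called from is not given in the sources used here. In the first the deposited values are a p-value per interval, up to 0.0499, with the gene identifier and the number of reads in the interval's name. Per the file's own name the caller was CLIPper, and 106 of its 8053 entries have p listed at 0. In the second the authors deposited a signal per interval, the peak height in tags, with an Entrez gene identifier and a P between 1e-100 and 0.0494, and 265 distinct intervals sit at the lowest P. Its caller is not given in the sources used here. Heights, reads and p-values are the authors' own and were used only to describe, rank or filter peaks within a list, and to set the lists beside each other. Because neither list records library totals, the depth per replicate is unknown.

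Entries that repeat an interval for another gene were counted once, which left 7651 and 1373 intervals. Entrez identifiers were matched to the RefSeq gene table of assembly GRCh38.p14, which named 1444 of 1454 entries (99.3%). That assembly differs from hg19, so the table served only for names, gene types, lengths and which genes contain one another, and none of its coordinates are given. It pairs no Ensembl identifiers with symbols, so genes of the CLIPper list were named only through a shared interval. Positions are 1-based hg19 as deposited. Whether peaks lie in exons, introns or UTRs, their sequence and their RNA structure were not analysed here for lack of an hg19 genome and annotation.

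The genes named were fixed by rule before the data were examined: the 10 with the most peaks in the height list, the 10 with the lowest P (ties by height), the 10 with the most CLIPper reads at a shared site, up to 4 members of each of 17 gene lists, and SNRPA1, PLEC, ERRFI1, RNU2-1, RNU2-2 (listed beforehand under its older symbol), MALAT1 and NEAT1. Genes named because they contain a U2 snRNA copy, HCN4, PCDHGA1, PCDHGA11 and CLEC18C were chosen after their values were seen. Of the 17 lists, 11 had at least 5 members among protein-coding and long noncoding RNA genes. The lists of other spliceosomal snRNA genes and of small nucleolar RNA genes are described with the small RNAs, the mitochondrially encoded genes had 0 members in the table, and the list of genes recalled from work on SNRPA1 has 3 members, of which 2 held a peak.

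Overlap was tested by moving each peak 500 to 5000 nt on its own strand (1000 draws). Correlations and differences of medians used 100000 permutations. Gene lists were compared with 10000 random lists matched on gene type and length decile. Tag numbers carry exact Poisson intervals and shares Wilson or Clopper-Pearson intervals at the 95% level, which cover counting error only. Calls used a threshold of 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

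Methods were first tested on simulated data. With 686 peaks placed on CLIPper intervals and the rest moved away, the overlap test found 686. The placed peaks were copies of those intervals, so this result checked only the code. The matched list test called 9 of 200 simulated lists with no effect and 187 of 200 with peaks 4 times as frequent. The median permutation called 1 of 100 sets with no shift and 100 of 100 with a shift of 2 on the log2 scale. Both simulations used fewer draws than the tests of the data, and weaker effects were not simulated. Alternatives covered the p threshold, merging of intervals, the definition of overlap, subsets of tall peaks, the matching on length and the counting of intervals that belong to several genes. For the last, 5 ways of counting were tried, and the one that counts an interval for every gene it is assigned to was kept because the planned number of peaks per gene is defined that way.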

Results

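The data map the RNA contacts of SNRPA1, a protein of the U2 small nuclear ribonucleoprotein (the particle that recognises the branch site of introns), in MDA-231-LM2 cells. This line is a lung-metastatic derivative of the human breast cancer line MDA-MB-231. Contacts were measured by irCLIP, in which RNA crosslinked to a protein is recovered with an antibody to that protein and sequenced. The 2 biological replicates form 1 group, and neither deposited peak list keeps them apart: the shorter is named as pooled, and the longer names no sample. No spread between replicates and no comparison between groups could therefore be computed, and the depth of each library is unknown. The intervals given below for tag numbers and densities cover counting error only.

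Peaks were low and spread over many genes, with a small number of very tall sites, and no control was analysed here that would separate contacts from background. The longer list, made with the peak caller CLIPper, held 7651 distinct intervals under 4848 Ensembl gene identifiers, with a median width of 33 nt and a median of 5 reads. The shorter list, here called the height list because it gives each peak's height in tags, held 1373 distinct intervals, also of median width 33 nt, with a median height of 4 tags. In the height list 89.8% of intervals were under 10 tags high, while 12 reached 100 or more. The 10 tallest intervals held 32.0% of the summed height. The height list named 1286 genes by Entrez identifier, of which 1207 were protein-coding and 49 were long noncoding RNA genes, and 89.3% of the genes held 1 peak.

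In the height list, the tallest peaks lay in genes that contain a copy of the U2 snRNA gene. The gene with the tallest peak was WDR74, a ribosome biogenesis factor gene that contains RNU2-2, at 1255 tags (95% Poisson interval 1187 to 1326; hg19 chromosome 11, 62609148 to 62609182, minus strand). It was followed by RUVBL1, which encodes an AAA+ ATPase and contains RNU2-37P, at 586 tags (chromosome 3, 127793975 to 127794007). LINC00910 contains RNU2-4P and reached 505 tags (chromosome 17, 41464652 to 41464685). RUBCNL with RNU2-6P reached 336 tags (chromosome 13, 46948618 to 46948651), IFT88 with RNU2-7P 281 tags (chromosome 13, 21186381 to 21186412) and GSKIP with RNU2-33P 269 tags (chromosome 14, 96851052 to 96851085). All 6 genes with the tallest peaks contained a U2 copy, as did 11 of the first 20. In the CLIPper list the WDR74 site had up to 2486 reads, and the strongest interval, with 2507 reads (chromosome 10, 103124665 to 103124673, minus strand), had no peak in the height list and no gene name here. The first genes of the height list without a U2 copy were SLC6A15, a neutral amino acid transporter gene, at 202 tags, and FGD6 at 161 tags.

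Over the 25 genes with a peak that contain a U2 copy, the median of the tallest peak was 43 tags, against 4 tags in 1253 other genes, a ratio of 10.8 (two-sided permutation test on log2 values, p = 1e-05, the smallest that 100000 draws can give). Both sets had similar median lengths, 124288 and 125278 nt. A peak of 20 or more tags was present in 17 of the 25 genes (68.0%) and in 31 of the others (2.47%), an odds ratio of 82.2 (95% interval 31.0 to 238; Fisher's exact test, adjusted p = 2.79e-19 over 12 tests, 11 families of small RNA copies and 1 set that combines several). Genes are not independent replicates. Among the U2 hosts SCHIP1 and IQCJ-SCHIP1 share 1 peak, and in the whole height list 39 intervals were assigned to more than 1 gene, each gene being counted separately. Of 46 protein-coding and long noncoding RNA genes that contain a U2 copy, 24 held a peak, against a mean of 5.83 in random genes matched on type and length (95% range 2 to 10, two-sided permutation p = 0.0002, the smallest that 10000 draws can give). Random genes absent from the annotation behind the height list, which is not given in the sources used here, could lower that mean. Containment was read from the GRCh38.p14 gene table and the peaks are in hg19, so whether each peak lies on the U2 copy itself was not analysed here. Containment also ignored strand, so a copy may lie on the strand opposite to that of its host gene. This comparison was chosen after the tallest peaks had been seen.

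**Figure D1:**
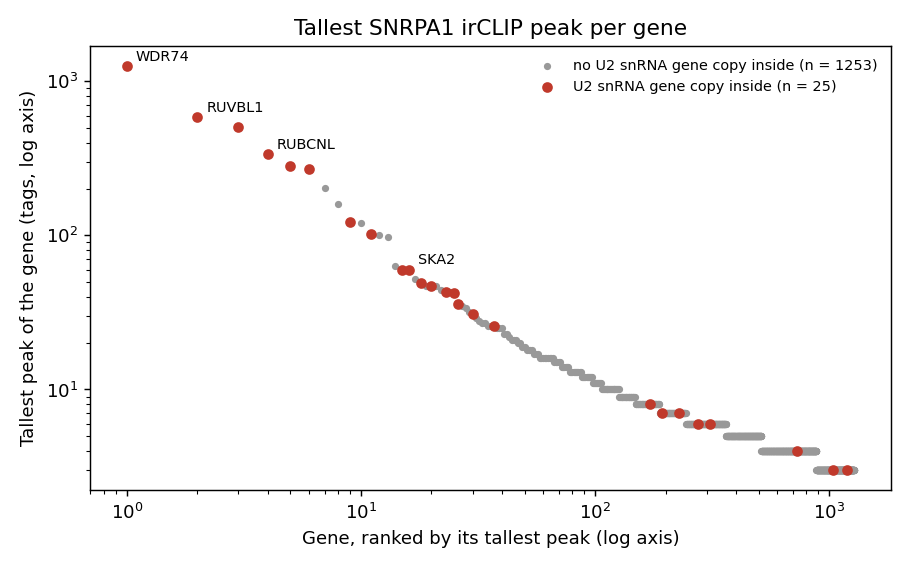
Each point is a gene of the height list, placed by its rank (x axis, log scale) and the height of its tallest peak in tags (y axis, log scale). Red points are the 25 genes that contain a U2 snRNA gene copy, with a median of 43 tags, and grey points the 1253 others, with a median of 4 tags.

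Genes that contain copies of other small RNA genes did not stand apart. The median tallest peak was 4 tags in the 122 genes that contain a U6 copy, 4 in the 69 with a 7SL copy and 4.5 in the 32 with a 7SK copy. No other family passed Fisher's exact test for peaks of 20 or more tags (adjusted p = 1 in each). Few peaks were assigned to small nuclear or nucleolar RNA genes themselves, and none to RNU2-1 or RNU2-2. The 7 such assignments fell on 4 sites of 3 to 6 tags. They named SNORD62A and SNORD62B (1 shared site), SNORD109A and SNORD109B (1 shared site), RNU5E-1 and RNU5D-1 (1 shared site) and RNU6-71P. Each shared site is 1 interval that carries both gene identifiers, and whether it lies on either gene was not analysed here. These are also multicopy genes, so the copy of origin is uncertain. The microRNA gene MIR548G, named after its value was seen, had 1 peak of 7 tags. The lists of 71 U2 snRNA genes and of 1071 7SK, 7SL, Y, vault and RNase RNA genes had no member with a peak assigned to it. A peak on a copy inside another gene can carry that gene's name, as the WDR74 site may for RNU2-2. Which of these small RNA genes the annotation behind the height list held is also not known here. The absence of assigned peaks therefore does not show that the U2 snRNA lacks contacts.

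PLEC and ERRFI1, named beforehand as genes recalled from work on SNRPA1, both held peaks. Whether that work used these same data is not known here, so their peaks are no independent test. PLEC, which encodes the cytoskeletal linker plectin, had 2, the taller at 6 tags (95% Poisson interval 2.20 to 13.1; chromosome 8, 144999329 to 144999362, minus strand). ERRFI1, which encodes a negative regulator of EGFR signalling, had 1 of 5 tags (1.62 to 11.7; chromosome 1, 8075255 to 8075286, minus strand). EGFR itself had 1 peak of 4 tags. MALAT1, a nuclear long noncoding RNA, had 1 peak of 6 tags (chromosome 11, 65269941 to 65269971, plus strand). SNRPA1 and NEAT1 were listed with 0 peaks. The most peaks in 1 gene were 10 in ANKRD30BL, all between positions 133010726 and 133013174 of chromosome 2, with 6 to 25 tags. MACROD2 followed with 5 and WWOX with 4, both very long genes.

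Of the lists fixed before the data were examined, 3 of the 11 that could be tested held more genes with a peak than random genes matched on type and length (permutation of gene labels within type and length decile, 10000 draws, two-sided, Benjamini-Hochberg adjusted over the 11). This test was added after the data had been seen, and expression is not corrected in it. Among chromatin and transcription regulator genes 19 of 53 held a peak, against a matched mean of 8.76 (adjusted permutation p = 0.0044). They included CUX1 with 2 peaks, the taller at 16 tags, the histone methyltransferase gene KMT2C with 2, and NCOA1 and SMARCA2 with 1 each. With only the 686 tallest peaks the count was 8 against 4.04, and the call was lost (adjusted permutation p = 0.241). Among hnRNP genes, which encode nuclear RNA-binding proteins, 5 of 30 held a peak against 1.20 (adjusted permutation p = 0.0337), among them HNRNPH1 with 7 tags, HNRNPK and PTBP2 with 5 each and HNRNPUL1 with 4. Without matching on length this call was lost (adjusted permutation p = 0.162). Among long noncoding RNAs of the nucleus 2 of 22 held a peak, MALAT1 and PVT1, against 0.0855 (adjusted permutation p = 0.0319). Random genes came from the 38386 protein-coding and long noncoding RNA genes of the GRCh38.p14 table. Which of them the annotation behind the height list held is not given in the sources used here. A gene it lacked could hold no peak, so matched means may be too low. The call for long noncoding RNAs is uncertain for this reason.

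The other 8 lists did not pass. Cytoskeleton and adhesion genes held a peak in 10 of 51 cases against 4.86 (adjusted permutation p = 0.0858), with 2 peaks each in MACF1, ACTN4 and PLEC. Without matching on length the adjusted permutation p was 0.0132. Lung metastasis and invasion genes did so in 5 of 38 against 2.51 (adjusted permutation p = 0.258), which included MMP14 with a peak of 6 tags. U2 snRNP and U2-associated protein genes gave 3 of 36 against 0.902 (adjusted permutation p = 0.225), namely SF3B3, DDX42 and U2SURP. Cytoplasmic ribosomal protein genes gave 3 of 89 against 0.731 (adjusted permutation p = 0.159), and translation factor genes 3 of 35 against 1.13 (adjusted permutation p = 0.258), where EIF4G3 had a peak of 34 tags. SR protein genes gave 1 of 19 (SCAF11), markers of other cell types 2 of 30 (RBFOX3 and SYT1) and histone genes 0 of 76, with adjusted permutation p of 0.809, 0.886 and 1. The test planned for these lists, whether members with a peak of the height list also hold a CLIPper interval, could be run on 4 lists and called 0 of them (Fisher's exact test, adjusted p = 1 in each, and 0 at an unadjusted p under 0.05), since 1242 of 1278 genes did.

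Nearly every peak of the height list lay on a CLIPper interval, while most CLIPper intervals had no peak in the height list. Of the 1373 intervals of the height list, 1335 (97.2%, 95% Wilson interval 96.2 to 98.0) overlapped a CLIPper interval by at least 1 nt on the same strand. When the peaks were moved by 500 to 5000 nt the mean was 1.25 overlaps (one-sided permutation test, p = 0.001, the smallest that 1000 draws can give). Neither list keeps the replicates apart and both were deposited for the same 2 libraries, so this overlap is no measure of replication. In the other direction 20.8% of the 7651 CLIPper intervals overlapped the height list. Across shared peaks, which are not independent replicates, height in tags and CLIPper reads correlated with a Spearman rho of 0.683 and a Pearson r of 0.827 on the log10 scale (p = 1e-05 for each, the smallest that 100000 permutations can give). Reads and tags may be unlike counts. The height list's name marks its tags as unique, and whether repeated reads were removed before the CLIPper list was called is not given in the sources used here. The median ratio of reads to tags was 1.67. It was 10 or more at 11 sites, the highest being 46.7 in HCN4, a pacemaker channel gene, with 140 reads and 3 tags.

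Genes with a peak were long. Their median length was 129.6 kb among protein-coding genes, against 24.1 kb for all 20056 protein-coding genes of the table. Across the 1278 genes with a peak and a known length, the number of peaks rose with length (Spearman rho = 0.179, permutation p = 1e-05, the smallest possible). Over all 20056 protein-coding genes, with those without a peak at 0, rho was 0.275 (permutation p = 1e-05, the smallest possible), a setting chosen after the data were seen. Among the 137 genes with at least 2 peaks the correlation did not pass (rho = 0.161, p = 0.0599). Every listed peak had a deposited P of at most 0.0494, which can depend on gene length. Peaks of 4 tags had a deposited P of 3.4e-06 in PCDHGA1 (182462 nt) and 2.64e-05 in PCDHGA11 (91925 nt). Length did not set it alone, as CLEC18C (13109 nt) had 6.45e-07 at 4 tags. Part of the relation with length may therefore come from this threshold, which was not tested. Per Mb of gene, density lay between 0.80 and 1.45 peaks in the 8 deciles of longer genes. It was 2.69 (95% Poisson interval 1.23 to 5.12) in the shortest decile and 1.92 (1.14 to 3.04) in the next. Those 2 values rest on 9 and 18 assignments and on how intervals that belong to several genes are counted: with only intervals assigned to 1 gene they were 0.299 and 0.747.

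**Figure D2:**
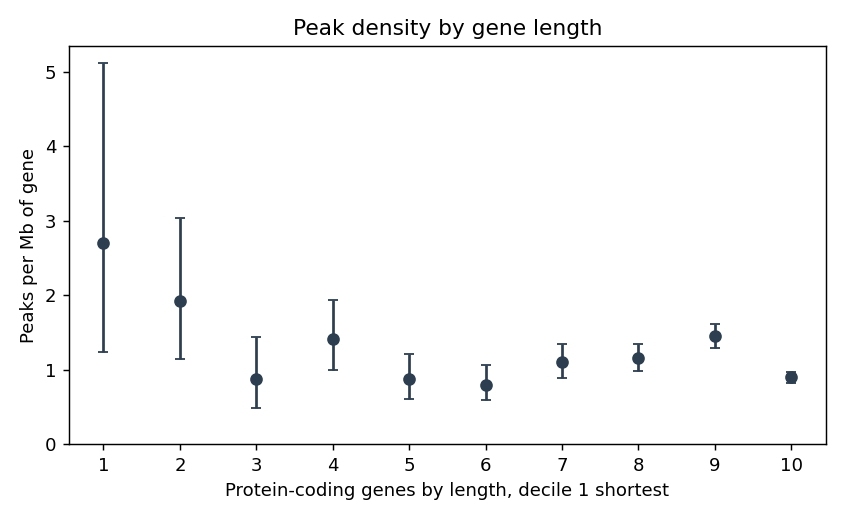
Points give the peaks of the height list per Mb of gene (y axis) in each length decile of protein-coding genes (x axis, 1 is shortest), and bars the 95% Poisson interval. The 8 longer deciles lie between 0.80 and 1.45 peaks per Mb, and the shortest decile, at 2.69, has the widest interval.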

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

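The region test was chosen after the data were seen. Both results here are signals in the CLIPper list at places that the comparisons by gene do not use. The CLIPper list held 48 intervals on the mitochondrial genome, with a median of 8 and at most 27 reads, while the height list had 0 there.

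Of 236 CLIPper intervals with 100 or more reads, 160 had no peak in the height list. The strongest had 2507 reads at chromosome 10, 103124665 to 103124673, minus strand. One candidate explanation is that a caller split broad regions into several sites. Splitting raised the number itself: joined within 50 nt, the 160 sites formed 53 regions. Of the 160, 28.1% (95% interval 21.3 to 35.8, too narrow because neighbouring sites are not independent) lay within 100 nt of a height-list peak, where a majority was required beforehand. Of the 53 regions 8 did (15.1%, 6.75 to 27.6), so most were not parts of a region with a height-list peak. Another is that the height list covers only some genes. The share of these sites whose Ensembl identifier also had a site with a height-list peak was 31.2% (24.2 to 39.0), and 20.8% of the regions (10.8 to 34.1), between the bounds of 10% and 50% set beforehand, so this stays open. Reads of the CLIPper list and unique tags of the height list may also be unlike counts, and this was not tested. No biological explanation was tested, since the design has 1 group.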

How the results depend on the processing

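Tests on U2 copies, on length-matched lists, on long genes, on the thresholds and merging of the height list, on repeated entries of either list, on every overlapping pair, on peak number against length over all protein-coding genes, on joined CLIPper sites and on the counting of shared intervals were chosen after the data were seen. Apart from the density over length deciles and the planned list test, which was near its ceiling and shows nothing about stability, 26 of 32 alternatives kept their direction and side of the threshold or, for counts, stayed within 1.5 times. One of the 26, the density ratio of long genes with peaks of at least 5 tags, did so by its p (0.0474) but not by its 95% interval (0.0594 to 1.09). The CLIPper list shrank from 7651 to 3825 intervals by construction when only the intervals with the lowest p were kept, and to 947 with p under 1e-10. The height list fell from 1373 to 653 intervals with P under 1e-5, and its sites assigned to small nuclear and nucleolar RNA genes from 4 to 1. Fewer peaks pass a stricter threshold by construction. The correlation of peak number with gene length lost its call among genes with at least 2 peaks (rho = 0.161, p = 0.0599), where 137 genes remained. Overlap of the lists ranged from 79.8% with those 3825 CLIPper intervals to 97.3% within 50 nt. The rho of strengths ranged from 0.636 without the tallest 5% to 0.718 over every overlapping pair. The number of length-matched lists called was 3, and 2 with the 686 tallest peaks. Without length matching it was again 3, but of other make-up: hnRNP genes were lost and cytoskeleton genes gained. Both settings are among the 26 by the number of lists called alone, although the call of single lists changed. The ratio of the highest to the lowest density over length deciles was 3.37 and ranged from 1.75 to 4.42 over the 5 ways of counting, and in 3 of the 4 alternatives the shortest decile turned from the highest to the lowest. The share of strong CLIPper-only sites near a height-list peak fell from 28.1% to 15.1% when sites were joined. Depth is unknown and limits every count of peaks. No paired analysis was possible because the samples form 1 group. Leaving out each replicate was not run because the lists do not keep them apart. Other windows, flanks and positions for annotation, sequence and structure were not run, as these need an hg19 genome.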

Other observations

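The tests of U2 copies were chosen after the pattern was seen, while the bound for long genes was set before its test. At the WDR74 site, CLIPper listed 21 intervals over 178 nt (chromosome 11, 62609104 to 62609281, minus strand), with the most reads, 2486, at positions 62609155 to 62609161. The 10 peaks of ANKRD30BL spanned 2449 nt of a gene that contains RNU6-1132P, RNA5-8SP5, LOC110467533 and MIR663B in the GRCh38.p14 table, and which of these, if any, the peaks lie on was not analysed here.

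Among peaks of the height list, the tallest lay in genes that contain a U2 snRNA gene copy, while several of the strongest CLIPper intervals had no gene name here. Gene length does not account for this: the highest median among 10000 draws of length-matched genes was 7 tags, against 43. Nor does a copy of just any other snRNA, 7SK or 7SL gene. Genes that contain copies of other spliceosomal snRNA, 7SK or 7SL genes and no U2 copy had an odds ratio of 0.852 (95% interval 0.253 to 2.29) for a peak of 20 or more tags, below the interval of the U2 hosts. Copies of U6, 7SL and 7SK lay in 122, 69 and 32 genes with a peak, but those of U1, U4 and U5 in only 9, 8 and 0. The abundance of the RNA of each copy was not measured, so whether abundant small nuclear RNAs of any kind give tall peaks stays open. It also stays open whether reads of one U2 snRNA aligned to several near-identical copies: 17 U2 host genes had a peak of 20 or more tags, and sequences, which could tell the copies apart, were not analysed here.

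Apart from the deciles of the shortest genes, peak density stayed between 0.80 and 1.45 per Mb. Background roughly proportional to gene length, whether or not the gene is expressed, could give such a range. The threshold on the deposited P may also bear on it. Density was not the same at all lengths, however: decile 9 was at 1.45 (95% Poisson interval 1.29 to 1.61) and decile 10 at 0.896 (0.827 to 0.970). Long genes of neurons (60 genes, 21 peaks) held 0.405 peaks per Mb, and long genes of most cell types (60 genes, 33 peaks) 1.32, a ratio of 0.308 (95% interval 0.169 to 0.549, exact binomial p = 2.76e-05 against equal density). The interval excludes 1, but its upper limit is above the bound of 0.5 set beforehand. The 2 lists were also not matched on length: they covered 51.8 and 25.1 Mb. As density differed between deciles 9 and 10, part of the ratio can come from length. Markers of other cell types held a peak in 2 of 30 cases, against a mean of 1.37 in genes matched on type and length. Background that ignores expression therefore stays open. With only peaks of at least 5 tags, 4 and 7 peaks were left and the ratio was 0.277 (exact binomial p = 0.0474), with an interval of 0.0594 to 1.09 that includes 1, so by that interval the difference did not hold. Expression was not measured here, and no biological explanation was tested.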
